A study of Mus musculus with 10 samples.

How the data were processed

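Purified neutrophils were profiled on 10 Illumina mouse bead arrays after Trizol extraction and Cy3 labelling, per the labels. The groups were fresh control (2 arrays), fresh tumor-bearing (2 arrays) and 6 cultured conditions with 1 array each, and no array was left out. For every probe the deposited table gives, per the file headers, the average signal intensity on the scanner scale, the number of beads, the standard error of the bead signals (other), and a detection p-value, the share of negative controls at least as bright. The detection p-values are multiples of 1 over 936, and the signals were checked to be neither background-subtracted nor normalized. A second table holds the authors' processed values on a log2 scale. These were checked to equal quantile-normalized log2 signals without background correction, with a largest difference of 0.00531, and each array correlated best with its own processed column (10 of 10). Partek is named in the submitters' notes, while its version and role, and the scanner software, are not given in the sources used here.

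Values were computed from the unprocessed signals in R 4.3.3 with limma 3.58.1, by the normexp correction with negative-control levels inferred from the detection p-values (nec, offset 16), log2 and quantile normalization over the 10 arrays. Of 45281 probes 34885 name 1 gene, 18 name several and 10378 name none, and the named probes cover 19057 genes. Probes were kept where the detection p-value was below 0.05 on at least 2 arrays of the fit, and each gene was read from the probe that names it alone with the highest mean over all arrays. Background correction widens changes of dim probes, quantile normalization removes differences in array brightness, and a single probe can miss a transcript variant, so the other detected probes of named genes are given where they differ by more than 1 on the log2 scale, and for some others. Where a gene was not detected in one group, a bound is given as "at least", with each array of that group set to no less than the lowest value detected on it. Genomic positions of probes were not used here, except for the order of genes in a single test.

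Tumor-bearing and control arrays were compared in a limma fit of the 4 fresh arrays. G-CSF, CCL2 and CCL5 effects came from an additive fit of the 6 cultured arrays, with 2 residual degrees of freedom. Whether chemokine effects differ with G-CSF was tested with 8 group means over 10 arrays, where the spread comes from the fresh pairs alone and the lone cultured arrays are assumed to vary like them. Untreated culture was compared with fresh control in a fit of all 10 arrays with the additive culture layout. Tests were two-sided, with empirical Bayes variances and Benjamini-Hochberg adjustment at 0.05. The CCL2, CCL5 and G-CSF effects share arrays and therefore chance values. Replicate numbers did not pair the fresh arrays, since replicate deviations of both groups correlated at 0.071 across probes. Errors are standard errors of the fit.

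Gene groups were 27 lists, 16 of processes and 11 of cell types, tested with camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over the lists of a comparison. With an estimated correlation camera tests on the residual degrees of freedom of the fit, 2 here and 4 in the culture comparison. A call lost with it therefore does not show that a list stayed still. Fry tests whether the members move one way on balance, without comparing them with other genes. Lists with fewer than 2 tested members had no set test, which left the progenitor list, with Kit alone tested, as a single gene. Markers of other blood cells, where counted together, are those of T, B and NK cells, monocytes, dendritic cells, eosinophils with basophils and mast cells, red cells and platelets. The progenitor list is not among them. The comparisons, lists, naming rule and alternatives were chosen before the data were examined. Named genes are, per comparison, the 10 largest rises and 10 largest falls among genes past the test whose groups do not overlap or whose matched pairs all change the same way. From each list up to 2 risers and 2 fallers with the smallest p are added, and the genes of the added factors and their receptors. Of the genes fixed for naming, 1 is not reported here. Where fewer genes pass, the 5 with the smallest p in each direction are given as values. Genes named outside this rule, such as Scgb1a1, Cdh1 and some list members, were chosen after their values were seen.

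The fits were tested on simulated data with 200 changed genes. Values were drawn independently from normal distributions with the real gene means and the empirical Bayes variances of each fit. Such data hold no correlation between genes, so recovery and false calls may differ on the real arrays. For tumor-bearing against control 13 of 67 genes changed 1.41-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, with 6 false calls. The G-CSF fit recovered 3, 64 and 66, with 4 false calls, and the CCL2 fit 3, 60 and 66, with 15. The G-CSF by CCL2 difference recovered 0 of 67, 13 of 67 and 59 of 66, with 8 false calls, and the culture comparison 1, 49 and 66, with 4.

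The alternatives were no background correction, median scaling, the authors' processed values, no filter on dim probes, a detection p-value below 0.01 on every array, every probe as its own feature, an intensity trend, other sets of arrays or terms, a replicate block, each array left out in turn, estimated correlations and adjustment over each list alone. A chip block was planned but not run, because the chip of each array is not given in the sources used here.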

Results

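Total RNA of purified mouse neutrophils was measured on 10 Illumina mouse bead arrays, each reading 45281 probes. The cells came from female nude NCR mice, an athymic strain that carries few T cells. In the first experiment, circulating neutrophils of control mice (2 arrays) and of mice bearing 4T1 tumors, grown from a mouse mammary carcinoma line (2 arrays), were frozen directly after purification. In the other, circulating neutrophils of control mice were cultured for 2 h in low-serum medium (0.5% fetal bovine serum) in 6 conditions with 1 array each. These were no addition, CCL2, CCL5, G-CSF, G-CSF with CCL2, and G-CSF with CCL5, with the chemokines at 20 ng/ml. The labels name human recombinant G-CSF as a treatment and list it after in vitro culture of cells of control mice, in the same form as the chemokines. They do not say separately whether it was added to the wells or given to the mice. CCL2 and CCL5 are chemokines that attract monocytes and lymphocytes, and G-CSF is the cytokine that drives neutrophil production.

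Between 13227 probes (cultured with CCL2) and 14846 probes (cultured with G-CSF and CCL5) were detected per array, 29.2% to 32.8% of all probes. Each probe was read from a median of 43 to 44 beads per array. Background signal was 97.3 to 101.8 on the fresh arrays, 96.0 to 104.8 on the cultured arrays without G-CSF and 107.0 to 120.0 on those with G-CSF. The 95th percentile of signal was 564 to 638 on the cultured arrays without G-CSF and 775 to 939.6 on those with it. Normalized values of the control pair correlated across probes at r = 0.987, and the probes are not independent replicates. The origin of the replicates is not stated, so each p-value measures only the spread between these samples, and the number of arrays limits the precision. In all, 8 comparisons were computed, each with 27 gene lists, and the gene sets from tumor-bearing mice were tested in 3 of the cultured effects.

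**Figure D1:**
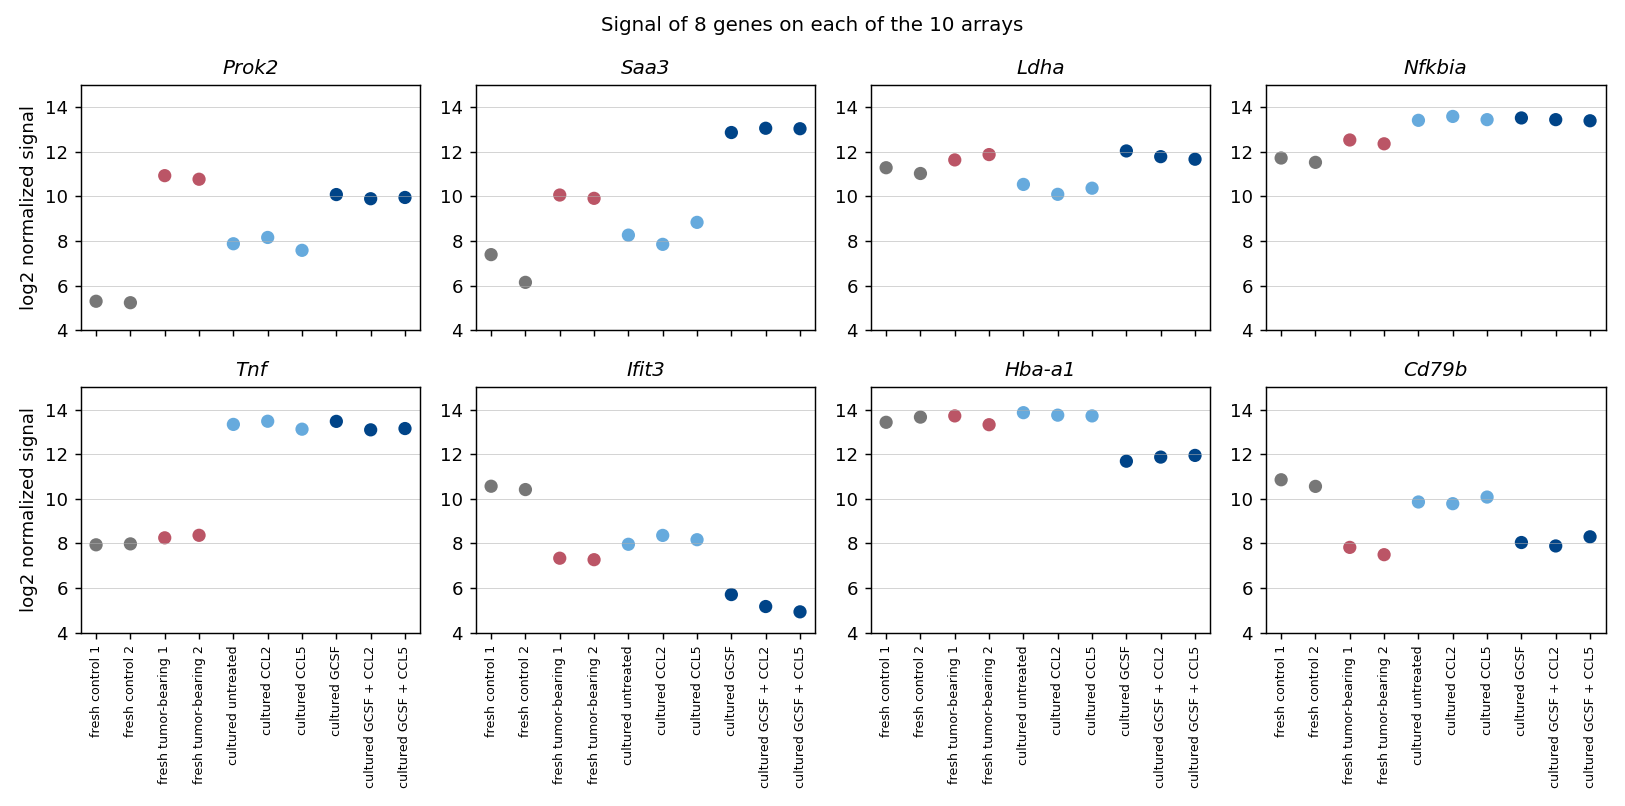
Log2 normalized signal (y axis) of 8 genes on each of the 10 arrays (x axis, grouped by condition), 1 dot per array. Prok2 was higher on both arrays of tumor-bearing mice than on both control arrays, and Ifit3 and Hba-a1 were lower on each cultured array with G-CSF than on its partner without it.

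The first comparison asked how circulating neutrophils of tumor-bearing mice differ from those of control mice. Prok2, which encodes the secreted myeloid chemoattractant prokineticin 2, rose 47.9-fold in tumor-bearing mice (log2 change 5.58 ± 0.19 SE, n = 2 and 2 arrays, limma adjusted p = 3.45e-09), and its other probe gave 5.51. Of 21 tested genes of glycolysis and hypoxia 13 rose and 1 fell, and all 6 B cell and 5 T cell markers tested fell. Camera called these 3 lists, and the calls were lost with an estimated correlation (adjusted p = 0.314 each), which tests on 2 residual degrees of freedom. Ifit3, an interferon-induced gene, fell by 3.19 on the log2 scale (SE 0.19, adjusted p = 3.69e-07), and its other probe gave -1.57. Csf3r, the G-CSF receptor, differed by 0.06 ± 0.18 (adjusted p = 0.852).

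Among the largest rises, Ambp, which encodes the precursor of a plasma protease inhibitor, rose by 4.54 ± 0.22 (log2, SE) and Xxylt1 by 3.86 ± 0.24. Tlr1, a receptor for bacterial lipopeptides, rose by 3.55 ± 0.18, Cpne8 by 3.50 ± 0.21, Wfdc18 by 3.48 ± 0.20 and Igfbp6, a binding protein of insulin-like growth factors, by 3.35 ± 0.18. Saa3, an acute-phase protein, rose by 3.22 ± 0.31 (adjusted p = 1.27e-05). Cnnm2 rose by 4.04 ± 0.19 on the probe tested, and its other probe gave 0.46. Kit, the stem cell factor receptor of progenitors and mast cells, was at least 9.25-fold higher, since it was not detected on the control arrays, and its other probe gave 0.45. The largest falls were those of Acot1, a fatty acyl-CoA hydrolase, with -3.85 ± 0.20 (its other probe -1.59), Ifit3, the T cell receptor segment Trbv13-2 with -3.08 ± 0.22, the B cell receptor component Cd79b with -3.05 ± 0.20 and Foxq1 with -3.04 ± 0.22. St6gal1 (-2.87), Rasgrp1 (-2.85), Chst3 (-2.78), the proton channel gene Hvcn1 (-2.77) and Snn (-2.75) followed.

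The 21 genes of glycolysis and hypoxia had a median change of 0.66 (13 rose and 2 fell adjusted over the list alone). Ankrd37, a hypoxia-induced gene, rose by 2.60 ± 0.22 and Pfkl, which encodes a phosphofructokinase subunit, by 1.10 ± 0.19, while Vegfa fell by 0.68 on the log2 scale and its other probe gave 0.17. The camera test of this list gave an adjusted p = 9.16e-04, against an adjusted p = 0.314 with an estimated correlation. Secondary and tertiary granule genes rose in 7 of 16 cases and fell in 0 (the same counts adjusted over the list alone; median 0.36), among them Ngp, a granule protein, by 1.85 ± 0.20 and Olfm4 by 1.17 ± 0.18. Their camera adjusted p was 0.00277, and the adjusted p = 0.314 with an estimated correlation. In the primary granule list 1 of 3 tested genes rose, the proteinase gene Prtn3, by 1.36 ± 0.23 (camera adjusted p = 0.501). On these same arrays 29 of 38 tested markers of other blood cells fell and 0 rose, with a median of -1.08. This count leaves out the progenitor list, whose only tested gene, Kit, rose. The 9 neutrophil markers had a median of 0.06, with 2 of them past the test (Mmp8 0.72 ± 0.20 and Il1r2 0.69 ± 0.18, both higher).

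Receptor and adhesion genes rose in 7 and fell in 2 of 21 cases (7 and 2 adjusted over the list alone; median 0.22; camera adjusted p = 0.00491, and adjusted p = 0.314 with an estimated correlation). Cxcr1, an interleukin 8 receptor, rose by 2.43 ± 0.18 and Csf2rb2 by 1.94 ± 0.19, while Ccr3 and Cxcr4 fell, Cxcr4 by 0.58 on the log2 scale (SE 0.20). Of 15 tested STAT3 and G-CSF receptor targets 7 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.49; camera adjusted p = 0.00493, and adjusted p = 0.314 with an estimated correlation). Il4ra rose by 2.23 ± 0.23 and the cell cycle inhibitor Cdkn1a by 1.31 ± 0.18, whereas Cish, a feedback inhibitor of cytokine signalling, changed by -1.12 ± 0.19 and Cebpd by -1.05 ± 0.21 on a probe whose partner gave 0.74. NF-kB targets rose in 5 and fell in 2 of 15 cases (8 and 2 adjusted over the list alone; median 0.45; camera adjusted p = 0.00935, and adjusted p = 0.314 with an estimated correlation), Rel by 1.08 ± 0.18 and Ier3 by 0.92 ± 0.19, against Cd83 with -1.50 ± 0.19. Among 22 immediate early genes 7 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.35; camera adjusted p = 0.00448, and adjusted p = 0.314 with an estimated correlation). Egr2 rose by 1.82 ± 0.20, and Egr3 rose 8.02-fold (SE 0.22 on the log2 scale) on a probe whose partner gave 0.37. Suppressive myeloid cell genes rose in 5 and fell in 2 of 12 cases (5 and 2 adjusted over the list alone; median 0.36; camera adjusted p = 0.0172, and adjusted p = 0.314 with an estimated correlation). Besides Prok2 and Il4ra, Nos2, Ptgs2 and Wfdc17 rose, while Cd274, which encodes the checkpoint ligand PD-L1, changed by -0.84 ± 0.19 and Tgfb1 by -0.70 ± 0.18. On the same arrays the other-cell markers had a median of -1.08.

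Every tested B cell marker fell (6 of 6, also adjusted over the list alone; median -2.46; camera adjusted p = 8.86e-07, and adjusted p = 0.314 with an estimated correlation), Cd22 by 2.50 on the log2 scale (SE 0.19). All 5 T cell markers fell too (5 adjusted over the list alone; median -1.58; camera adjusted p = 3.43e-04, and adjusted p = 0.314 with an estimated correlation). Il7r, which encodes the interleukin 7 receptor, was at least 3.25-fold lower and Cd3g, a chain of the T cell receptor complex, at least 3.03-fold lower, as neither was detected in tumor-bearing mice. Dendritic cell and MHC class II genes fell in 4 of 6 cases (4 adjusted over the list alone; median -1.74; camera adjusted p = 0.0031, and adjusted p = 0.336 with an estimated correlation), with H2-Ab1 at -2.52 ± 0.19 and Cd74 at -2.38 ± 0.21 (other probes -2.01 and -1.25). Monocyte and macrophage markers fell in 4 of 7 cases (4 adjusted over the list alone; median -0.66; camera adjusted p = 0.0198, and adjusted p = 0.314 with an estimated correlation), NK cell markers in 2 of 3 (2 adjusted over the list alone; median -1.77; camera adjusted p = 0.0228, and adjusted p = 0.314 with an estimated correlation), and eosinophil, basophil and mast cell markers in 3 of 4 (3 adjusted over the list alone; median -0.82; camera adjusted p = 0.0388, and adjusted p = 0.372 with an estimated correlation). Ly86 stood at -1.84 ± 0.19, Fn1 at -1.69 ± 0.19, the cytotoxic granule gene Nkg7 at -1.77 ± 0.21 and Klrd1 at -2.25 ± 0.19. Erythroid markers fell in 3 of 4 cases (3 adjusted over the list alone), with the heme synthesis gene Alas2 at -1.68 ± 0.25, and platelet markers in 2 of 3 (2 adjusted over the list alone), but neither list passed camera (adjusted p = 0.0675 and 0.0735).

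Interferon-response genes fell in 6 and rose in 3 of 21 cases (6 and 3 adjusted over the list alone; median -0.31), and camera gave an adjusted p = 0.0756, while fry, which asks whether the members move one way on balance, gave 0.0144. Cmpk2 fell by 2.22 on the log2 scale (SE 0.21), and Gbp3 rose by 1.19 ± 0.20. Cytokine and chemokine genes went both ways, with 3 risers and 4 fallers among 18 (3 and 4 adjusted over the list alone; camera adjusted p = 0.658). The neutrophil chemoattractants Cxcl1 and Cxcl2 rose by 1.47 ± 0.22 and 1.17 ± 0.18, Ccl2 was at least 1.65-fold higher, and Ccl5 fell by 2.40 on the log2 scale (SE 0.19). In the heat shock and unfolded protein response list 6 of 14 genes rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.0675), the chaperone gene Hspa1a by 2.13 ± 0.18. Antioxidant genes rose in 2 and fell in 2 of 12 cases (4 and 5 adjusted over the list alone; camera adjusted p = 0.895; median -0.07 and mean 0.03, the median being 0.01 under median scaling), with Gclm up by 2.44 ± 0.18 and the cystine transporter gene Slc7a11 at -1.72 ± 0.19 (other probes -0.69 and -0.64). Apoptosis regulators (2 rose and 3 fell of 16; 3 and 4 adjusted over the list alone; median -0.06, and 0.17 under median scaling), MHC class I genes (0 rose and 2 fell of 12, the same adjusted over the list alone), cell cycle genes (1 rose and 2 fell of 10, the same adjusted over the list alone) and NADPH oxidase genes (0 rose and 1 fell of 6, the same adjusted over the list alone; median -0.10, and 0.15 under median scaling) did not pass camera (adjusted p from 0.541 to 0.965). Among 3 epithelial markers 0 passed limma, over all genes or adjusted over the list alone, and 1 of them, Cdh1 at -0.52, had an unadjusted p below 0.05 (0.0255).

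In limma 2086 of 8019 tested genes differed, 868 higher and 1218 lower. Of these, 287 were at least 2-fold higher and 445 at least 2-fold lower. Under median scaling 2165 genes passed and 50.8% of them were higher, against 41.6%. At an unadjusted p below 0.05 there were 3065 genes, where chance alone would give about 401. The count was 1351 without the first array of tumor-bearing mice and 1175 without the second. For 637 of the 733 called genes with further detected probes, every further probe had the same direction.

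The second comparison asked what G-CSF changed in cultured neutrophils, over 3 arrays with it and 3 without. Saa3, the acute-phase gene, rose 25.4-fold with G-CSF (log2 change 4.67 ± 0.21 SE, n = 3 and 3 arrays, limma adjusted p = 2.99e-05). Nupr1, a stress-induced chromatin protein, rose by 3.77 ± 0.16 and Chil3, a secreted chitinase-like protein of myeloid cells, by 2.93 ± 0.19 (other probes 1.61 and 2.49). Of 19 tested interferon-response genes 12 fell and 1 rose, and all 4 erythroid and 4 T cell markers tested fell. Camera called these 3 lists, and the calls were lost with an estimated correlation (adjusted p = 0.345 each), which tests on 2 residual degrees of freedom. The largest single fall was that of Nt5e, an ectoenzyme that makes adenosine, with -3.44 ± 0.20. Csf3r stood at -0.10 ± 0.15 (adjusted p = 0.688). Arrays with G-CSF were brighter, and scaling each array to 1 median in place of quantile normalization moved the median change of all genes from 0.06 to 0.41. Under it 4512 genes passed, of which 88.9% were higher, so changes are given relative to the quantile-normalized distribution. The median is taken over all probes and lies near background, with a signal of 108.2 against 104.8 untreated and 121.5 against 117.1 with G-CSF alone. Median scaling therefore leaves differences in the brightness of detected genes in place.

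Further large rises were those of Casp6, an executioner caspase, by 3.02 ± 0.16, Dpep2 by 2.98 ± 0.22, Igfbp6 by 2.86 ± 0.18 and Mfsd7a by 2.77 ± 0.17, with other probes of Mfsd7a between 0.44 and 3.01. Kit was at least 7.81-fold higher (its other probe gave 0.01), Wfdc18 at least 5.95-fold and Chil4 at least 5.50-fold, none of them detected without G-CSF. Prok2 rose by 2.10 ± 0.18, the heme oxygenase gene Hmox1 by 2.00 ± 0.16 and Wfdc17 by 1.80 ± 0.15. Among the largest falls were Ifit3 with -2.89 ± 0.22 (its other probe -0.92), Cmpk2 with -2.86 ± 0.19, Tnfsf13b, the B cell survival factor BAFF, with -2.73 ± 0.16, and Fut4, a fucosyltransferase, with -2.59 ± 0.18. Rsad2 (-2.56), Alas2 (-2.51), the costimulatory gene Cd80 (-2.45, its other probe -0.43), Eml1 (-2.44) and Cass4 (-2.41) followed.

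The 19 interferon-response genes had a median of -1.25, or -0.78 under median scaling (12 fell and 1 rose, also adjusted over the list alone). Camera gave an adjusted p = 5.66e-07, and the adjusted p = 0.345 with an estimated correlation. Markers of other blood cells fell on the same arrays in 24 of 36 cases and rose in 0, with a median of -0.98. Under median scaling 19 fell and 6 rose. These counts leave out the progenitor list, whose only tested gene, Kit, rose with G-CSF. All 4 erythroid markers fell (4 adjusted over the list alone; median -1.79; camera adjusted p = 4.87e-05, and adjusted p = 0.345 with an estimated correlation), Hba-a1, which encodes alpha globin, by 1.94 on the log2 scale (SE 0.16). T cell markers fell in 4 of 4 cases (4 adjusted over the list alone; median -1.26; camera adjusted p = 2.46e-04, and adjusted p = 0.345 with an estimated correlation), Cd3d by 2.28 on the log2 scale (SE 0.16). B cell markers fell in 5 of 6 cases (6 adjusted over the list alone; median -1.37; camera adjusted p = 4.87e-05, and adjusted p = 0.345 with an estimated correlation), with Cd79b at -1.83 ± 0.15 and Fcrla at -1.66 ± 0.16. Dendritic cell and MHC class II genes fell in 5 of 6 (5 adjusted over the list alone; median -0.98; camera adjusted p = 2.11e-04, and adjusted p = 0.345 with an estimated correlation), among them Ciita, the master regulator of MHC class II genes, with -1.78 ± 0.17 (its other probe -0.45). Eosinophil, basophil and mast cell markers fell in 2 of 4 (2 adjusted over the list alone; median -0.86; camera adjusted p = 0.016, and adjusted p = 0.383 with an estimated correlation).

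NK cell markers fell in 2 of 3 cases (2 adjusted over the list alone) and monocyte and macrophage markers in 2 of 7 (3 adjusted over the list alone; median 0.02, mean -0.34), neither past camera (adjusted p = 0.175 and 0.365). The median of the 9 neutrophil markers was -0.02, and 0.26 under median scaling; Mmp8 rose by 1.13 ± 0.21 and Retnlg by 0.60 ± 0.16, while Cxcr2, a receptor for CXC chemokines, fell by 0.90 on the log2 scale (SE 0.16). Of 2 platelet and 2 epithelial markers, 0 passed limma over all genes or adjusted over the list alone, and 1 of them, Itga2b at 0.42, had an unadjusted p below 0.05 (0.0341).

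Immediate early genes fell in 9 of 23 cases and rose in 0 (9 and 1 adjusted over the list alone; median -0.44, and 0.08 under median scaling; camera adjusted p = 2.46e-04, and adjusted p = 0.383 with an estimated correlation). Egr2 changed by -1.50 ± 0.16 and Fosl2 by -1.23 ± 0.16. Cytokine and chemokine genes fell in 9 and rose in 3 of 23 (11 and 4 adjusted over the list alone; median -0.45, and -0.10 under median scaling; camera adjusted p = 0.0116, and adjusted p = 0.381 with an estimated correlation). Osm, which encodes oncostatin M, stood at -1.70 ± 0.16, Tnfsf14 at -1.58 ± 0.16 (other probes -1.25 and -0.23) and Ccl5 at -0.98 ± 0.17, while Ccl2 was at least 1.34-fold higher. Receptor and adhesion genes fell in 7 and rose in 1 of 22 (7 and 1 adjusted over the list alone; median -0.16, and 0.20 under median scaling; camera adjusted p = 0.0319, and adjusted p = 0.477 with an estimated correlation), with the endotoxin receptor gene Tlr4 at -1.47 ± 0.15 (other probes -1.29 and -0.26). On the same arrays the other-cell markers had a median of -0.98.

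Secondary and tertiary granule genes rose in 9 and fell in 4 of 17 cases (10 and 4 adjusted over the list alone; median 0.56; camera adjusted p = 0.0773). Chil3 and the neutrophil surface protein gene Cd177, which rose by 1.59 ± 0.15, were among the risers, and Adam8 fell by 1.59 on the log2 scale (SE 0.16). Glycolysis and hypoxia genes went both ways, with 4 risers and 5 fallers among 21 (4 and 5 adjusted over the list alone; median 0.05 and mean -0.01; camera adjusted p = 0.522). Ldha, which encodes lactate dehydrogenase A, rose 2.82-fold (SE 0.16 on the log2 scale) and Pfkl by 1.06 ± 0.17, while Vegfa changed by -1.14 ± 0.16. STAT3 and G-CSF receptor targets had 3 risers and 3 fallers among 15 (the same adjusted over the list alone; median -0.12, and 0.32 under median scaling), and Cdkn1a rose by 1.05 ± 0.16. Apoptosis regulators rose in 5 and fell in 1 of 17 (7 and 2 adjusted over the list alone), with the proapoptotic gene Bbc3 up by 1.85 ± 0.16 on a probe whose partner gave -0.10. NF-kB targets rose in 3 of 17 (2 adjusted over the list alone), suppressive myeloid cell genes rose in 4 and fell in 2 of 13 (4 and 2 adjusted over the list alone), and antioxidant genes rose in 3 and fell in 1 of 13 (4 and 2 adjusted over the list alone), with Slc7a11 at -1.03 ± 0.16. Among 7 NADPH oxidase genes the oxidase subunit gene Cybb rose by 1.12 ± 0.23, and Prtn3 of the primary granule list was at least 1.69-fold higher. These lists, and those of cell cycle, heat shock and MHC class I genes with at most 2 members past the test each, did not pass camera (adjusted p from 0.244 to 0.786).

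Limma called 2485 of 8610 tested genes, 1425 higher and 1060 lower with G-CSF, and 2484 of them changed the same way in all 3 matched pairs. Of these, 347 were at least 2-fold higher and 371 at least 2-fold lower. At an unadjusted p below 0.05 there were 3525, where chance alone would give about 430.5. The fit pools the spread of 6 single arrays with 2 residual degrees of freedom. The count was 1420 without the untreated cultured array or without its partner, the array with G-CSF alone. These are not 2 separate checks, since leaving out either array of a matched pair gives the same G-CSF fit. Every further probe had the same direction for 909 of 1043 called genes that have one.

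**Figure D2:**
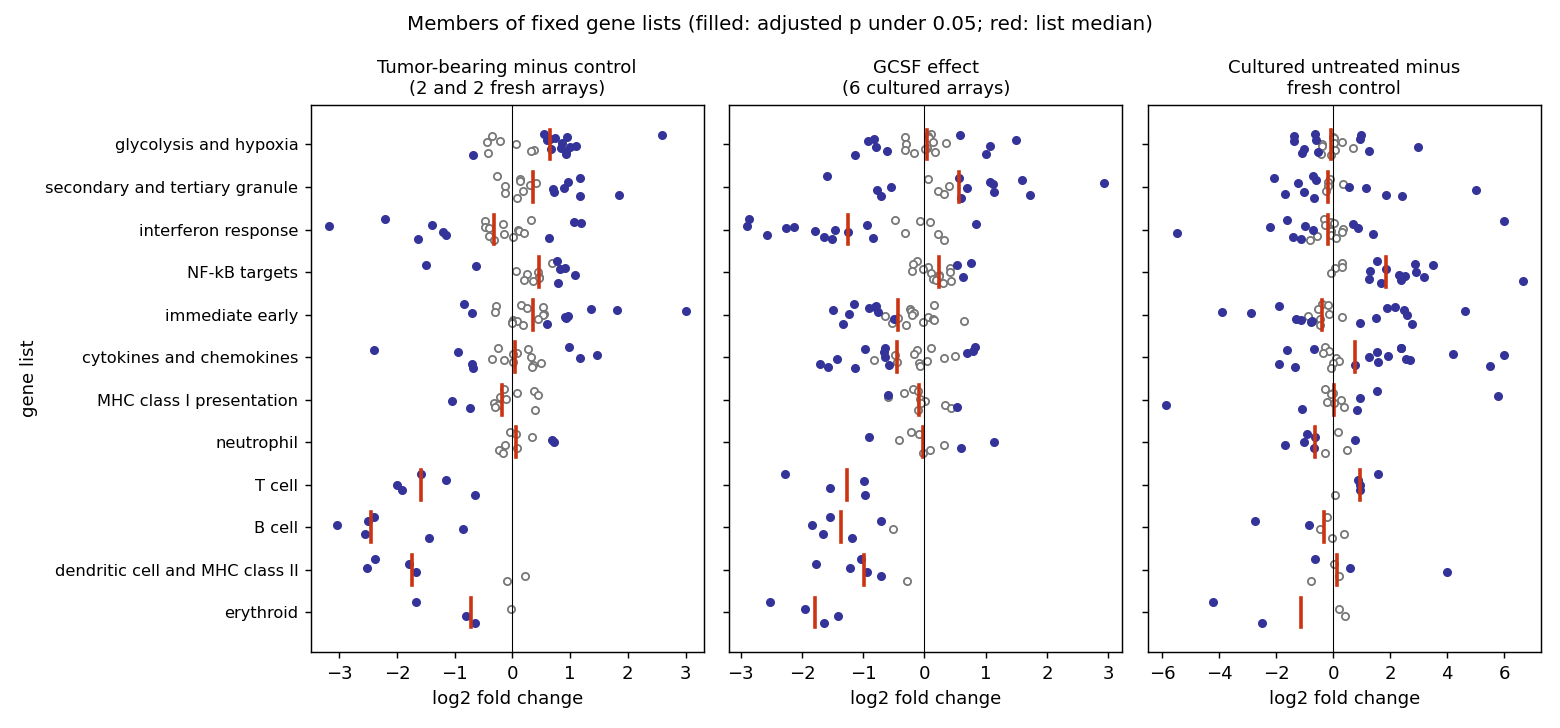
Log2 change (x axis) of each tested member of 12 gene lists (y axis). The panels show tumor-bearing against control mice, G-CSF in culture, and untreated culture against fresh control cells. Filled points passed limma at the adjusted level and red bars are list medians. Interferon-response genes have medians of -0.31 in tumor-bearing mice and -1.25 with G-CSF, and NF-kB targets a median of 1.85 in culture.

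CCL2 and CCL5 were compared with no chemokine, each over 2 pairs of cultured arrays, to ask what either changes in cultured neutrophils. The fit averages the pairs with and without G-CSF. Its 2 residual degrees of freedom hold any difference between these pairs as well as the spread between arrays. A gene not called here may therefore still respond to a chemokine in 1 of the settings. Of the receptor genes of CCL2 and CCL5, Ccr1 and Ccr2 were detected on 0 of the 10 arrays and Ccr3 on 6. With CCL2, Gper1, an estrogen receptor gene, stood at 0.98 ± 0.20 and Fez2 at -1.07 ± 0.22, neither past the test (adjusted p = 0.947 each). Utrn (0.95), Fut8 (0.94), Nrg1 (0.82) and Crtc2 (-0.97) also had small unadjusted p-values. The 23 cytokine and chemokine genes had a median of 0.20 with CCL2 and 0 of them passed limma, also adjusted over the list alone; camera gave an adjusted p = 0.00458, and adjusted p = 0.983 with an estimated correlation (fry adjusted p = 0.667). Limma called 0 of 8610 genes for CCL2, against 437 at an unadjusted p below 0.05, where chance alone would give about 430.5. Without the array with CCL2 alone 1 gene passed, Scgb1a1, named after its value was seen, at 3.10 (adjusted p = 0.0087).

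With CCL5, Dennd6b stood at 0.99 ± 0.21, Pheta1 at 0.94 ± 0.19 and Selenow at -0.99 ± 0.23 (adjusted p = 0.993 each). The eosinophil granule gene Prg2 passed when adjusted over the list alone, at 0.89 (adjusted p = 0.0255), and was the only list member to do so with CCL5. Limma called 0 genes for CCL5, against 351 at an unadjusted p below 0.05. Between CCL2 and CCL5 limma called 0 genes, against 479 at an unadjusted p below 0.05; the chemokine receptor gene Ccr7 stood at -1.06 ± 0.20, Slc39a1 at -1.11 ± 0.26 and Mgst3 at 0.94 ± 0.21 (adjusted p = 0.891 each). The list members Mcm6 (0.90) and Itga2b (-0.58) passed when adjusted over the list alone, and were picked for naming after their values were seen. Without the array with G-CSF and CCL2, 1 gene passed between the chemokines, again Scgb1a1, at -3.30 (adjusted p = 0.00465). The typical 95% interval of a chemokine effect reached 0.48 to either side on the log2 scale. Under median scaling the median change of all genes was -0.16 with CCL2 and -0.18 between the chemokines.

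Whether the chemokine effects differ with G-CSF was tested against the spread of the fresh pairs. Basp1 (2.24 ± 0.42), Itpr3 (1.95 ± 0.39), Ccr3 (-1.85 ± 0.40) and Psmb5 (-2.22 ± 0.42) had the smallest p-values or were fixed for naming in the G-CSF by CCL2 difference, where limma called 0 of 9744 genes (smallest adjusted p = 0.306), against 884 at an unadjusted p below 0.05 and about 487 by chance. Leaving out the first or the second fresh control array gives the same fit of this difference, so these are not separate checks. Its spread then comes from the tumor-bearing pair alone. The genes past the test in it were Basp1 (2.24), Psmb5 (-2.22) and, named after its value was seen, Scgb1a1 (5.81). The 17 NF-kB targets had a median difference of -0.33 with 0 past limma or adjusted over the list alone, and camera gave an adjusted p = 0.0199, against adjusted p = 0.718 with an estimated correlation; fry gave an adjusted p = 0.00702. Adjusted over the list alone 5 calls were made, Cybb (-1.19), Cxcr4 (-1.41), Irf8 (-1.85) and, in both its lists, Ccr3, the first 3 of these genes named after their values were seen. Ccr3 lay below the lowest value detected on the untreated array (4.64 against 4.85) and on that with G-CSF and CCL2 (4.75 against 4.82). Its values here and in the CCL5 difference therefore rest partly on signal near background. For G-CSF by CCL5, Lin28a stood at 2.14 ± 0.36 (its other probe 0.22), Cers6 at -2.16 ± 0.40 (its other probe -0.08) and Ccr3 at -1.94 ± 0.40, and limma called 0 genes (smallest adjusted p = 0.359), against 707 at an unadjusted p below 0.05. Adjusted over the list alone 6 calls were made, including the NK cell genes Klrd1 (1.04) and Nkg7 (1.03). The NK cell list, with 3 tested genes and a median of 1.03, had a camera adjusted p = 0.0337, and adjusted p = 0.888 with an estimated correlation (fry adjusted p = 0.528). The typical 95% interval of these differences reached 0.83 to either side.

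Genes that differed in tumor-bearing mice were then followed in culture, to ask whether G-CSF or a chemokine moves them. Across 7334 genes tested in both experiments, which share no array, 227 were higher in both tumor-bearing mice and G-CSF (about 140.0 by chance, Fisher adjusted p = 1.41e-15) and 354 were lower in both (about 157 by chance). Under median scaling 591 were higher in both, against about 529 by chance. Prok2 (5.58 in tumor-bearing mice and 2.10 with G-CSF), Saa3 (3.22 and 4.67), Igfbp6 (3.35 and 2.86), Wfdc18 and Ngp (1.85 and 1.73) were among the shared rises. Shared falls included Ifit3 (-3.19 and -2.89), Cmpk2 (-2.22 and -2.86), Foxq1 (-3.04 and -2.13) and Alas2 (-1.68 and -2.51). The set higher in tumor-bearing mice had a median of 0.19 with G-CSF, with 62.6% of 781 genes above 0 (camera adjusted p = 0.014, and adjusted p = 0.332 with an estimated correlation; fry adjusted p = 0.0292). The lower set had a median of -0.19, with 61.3% of 1156 genes below 0 (camera adjusted p = 2.25e-07, and adjusted p = 0.302 with an estimated correlation). Across genes the changes correlated at r = 0.295 (Spearman rho 0.168), and genes are not independent replicates. Opposite calls were made for 218 genes, 88 of them higher in tumor-bearing mice (about 106 by chance) and 130 lower (about 207 by chance). Markers of other blood cells had medians of -1.08 in tumor-bearing mice and -0.98 with G-CSF. The higher set lost its call without the untreated cultured array (median 0.15, camera adjusted p = 0.0568) or without the array with G-CSF alone (0.15, camera adjusted p = 0.0927). Both give the same G-CSF fit and count as 1 check. Their p-values were adjusted together with those of the chemokine effects, whose fits do differ.

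With CCL2 the higher and lower sets had medians of 0.01 and -0.01 (camera adjusted p = 0.798 and 0.893), and with CCL5 -0.01 and 0.03 (adjusted p = 0.748 and 0.356). Across genes the correlation with the tumor-bearing change was 0.020 for CCL2 and -0.054 for CCL5. The difference between the G-CSF and chemokine set results was not tested.

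**Figure D3:**
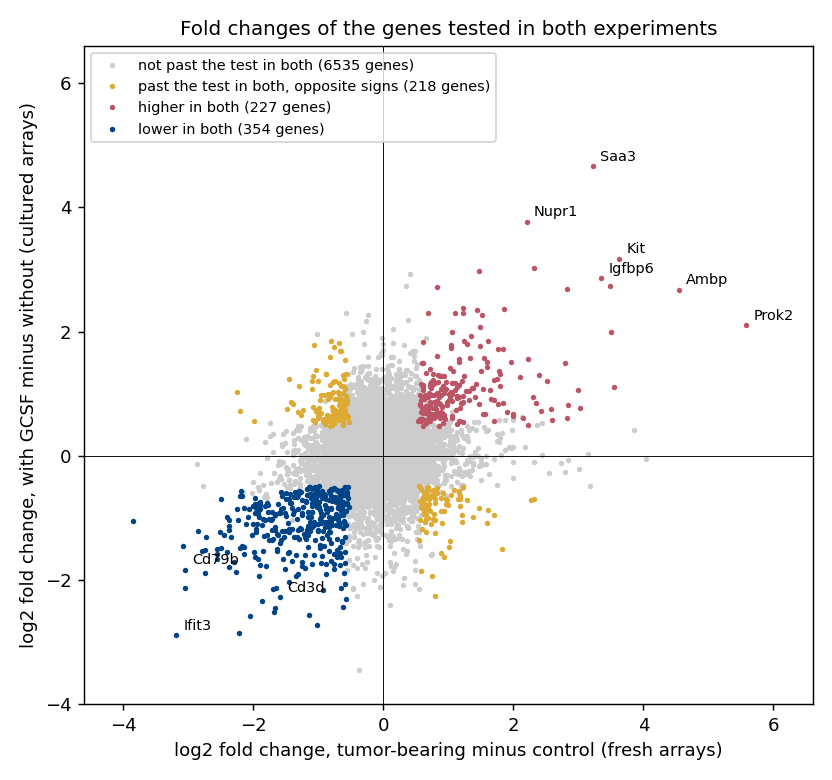
Log2 change with G-CSF in culture (y axis) against log2 change in tumor-bearing mice (x axis) for 7334 genes, 1 point per gene, colored by whether both changes passed limma. The 227 genes higher in both and the 354 lower in both lie in the upper right and lower left, against 218 with opposite directions.

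The last comparison set untreated cultured neutrophils (1 array) against fresh control neutrophils (2 arrays), which differ in culture and in anything else that separated the experiments. The untreated level was estimated from all 6 cultured arrays in an additive fit, and values given as "at least" come from the untreated and control arrays alone. In culture Tnf rose 44.7-fold (log2 change 5.48 ± 0.21 SE, limma adjusted p = 9.55e-10), Cxcl10, a chemokine induced by interferon, rose 63.1-fold (log2 change 5.98, and 5.74 from the untreated and control arrays alone), and the signalling adaptor gene Traf1 was at least 69.7-fold higher on the probe tested (its other probe had a log2 change of 4.47). The immediate early gene Fos fell by 3.92 on the log2 scale (SE 0.23), and Csf3r by 0.93 (SE 0.19; other probes from -0.93 to 0.11). Gpr84 (5.63 ± 0.21), Acod1, which makes itaconate (5.29 ± 0.20), Bcl2a1c (4.73 ± 0.20), and Havcr2, at least 22.5-fold, were also higher. H2-K1 had a change of 5.76 ± 0.24 on the probe tested while its other probes gave -2.83 and 0.60, H2-Q6 rose by 5.64 ± 0.20, and Ltf, which encodes lactoferrin, by 5.02 ± 0.20 on a probe whose partner gave 0.30. Lower in culture were Pdlim4 (at least 59.2-fold on the probe tested, while its other probe had a log2 change of -3.39), Foxd4 (at least 47.9-fold), Tmem71 (at least 32.1-fold) and Abhd16a (at least 23.7-fold), which were not detected on the cultured array. The immunoproteasome gene Psmb9 stood at -5.88 ± 0.23, Oasl2 at -5.48 ± 0.21 (other probes -3.83 and -2.71), Psmd8 at -4.41 ± 0.27 and Alas2 at -4.24 ± 0.26.

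NF-kB targets rose in 13 of 17 cases and fell in 0 (13 and 0 adjusted over the list alone; median 1.85; camera adjusted p = 2.86e-10, and adjusted p = 0.384 with an estimated correlation), among them Sod2 by 3.19 ± 0.20. Cytokine and chemokine genes rose in 12 and fell in 4 of 23 (12 and 4 adjusted over the list alone; median 0.75; camera adjusted p = 0.00563, and adjusted p = 0.384 with an estimated correlation), with Osm at -1.91 ± 0.20 and Ccl6 at -1.64 ± 0.21. On the same arrays the neutrophil markers had a median of -0.65, with 5 of 9 lower and 1 higher. Markers of other blood cells had a median of -0.28, with erythroid markers at -1.15 and T and B cell markers together at 0.05. Among the T cell markers 4 of 5 rose (Cd3d by 1.56 ± 0.20). Receptor genes rose in 8 and fell in 4 of 22 (9 and 4 adjusted over the list alone), with Tlr2 up by 1.85 ± 0.22. Immediate early genes rose in 8 and fell in 7 of 23 (8 and 9 adjusted over the list alone; median -0.41 and mean 0.15), from Egr3, at 4.62 ± 0.23 on a probe whose partner gave 0.36, to Fosb at -2.87 ± 0.24. Secondary and tertiary granule genes rose in 5 and fell in 7 of 17 (5 and 7 adjusted over the list alone; median -0.19 and mean 0.14), with Anxa1 at -2.09 ± 0.21 and the gelatinase gene Mmp9 at -1.71 ± 0.22. Glycolysis and hypoxia genes rose in 4 and fell in 7 of 21 (5 and 7 adjusted over the list alone), and Pfkp rose by 2.99 ± 0.22 (its other probe 1.78). Interferon-response genes rose in 4 and fell in 7 of 22 (4 and 9 adjusted over the list alone), and apoptosis regulators rose in 8 and fell in 3 of 17 (8 and 3 adjusted over the list alone). Slc7a11 rose by 4.01 ± 0.20 (other probes 0.74, 2.72 and 4.39), Prok2 by 2.66 ± 0.21 and Cd274 by 1.91 ± 0.20, while Socs3 fell by 2.60 on the log2 scale (SE 0.21) and the B cell gene Cd22 by 2.76 (SE 0.19; its other probe gave -1.42). Besides the NF-kB and cytokine lists, 0 of the lists passed camera (smallest adjusted p = 0.0837, T cell markers), and 3 of them had an unadjusted camera p below 0.05.

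Limma called 3335 of 9744 tested genes in culture, 1599 higher and 1736 lower, with 849 at least 2-fold higher, 902 at least 2-fold lower and 31 changed at least 16-fold. At an unadjusted p below 0.05 there were 4202. Under median scaling, where the median change of all genes was -0.13, 3410 genes passed and 35.0% of them were higher, against 47.9%. Without the untreated cultured array the level is taken from the additive layout of the other cultured arrays, and 2168 genes passed. For 1066 of 1477 called genes with further probes, every further probe had the same direction.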

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

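The tests on different cell preparations, on the overlap within bands of signal and on the share of neutrophils were chosen after the results were seen; the other tests were fixed before theirs. Probes that name no single gene lie outside the comparisons, and limma called 655 of 2360 of them between tumor-bearing and control mice (284 higher, 371 lower) and 622 of 2388 with G-CSF (253 higher, 369 lower).

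Markers of other blood cells were lower on the cultured arrays with G-CSF, in 24 of 36 cases. The median marker change was -0.98 with G-CSF, against 0.02 with CCL2 and 0.09 with CCL5. Different cell preparations for the arrays with and without G-CSF stay open, because this value restates the pattern and would be the same for an effect of G-CSF on the genes. Red cell markers had a median of -1.79 and T and B cell markers of -1.36 (exact two-sided permutation test p = 0.107), the abundant globin gene Hba-a1 fell by 1.94 on the log2 scale, and neutrophil markers had a median of -0.02, or 0.26 under median scaling. For array brightness, the marker median was -0.49 without background correction, just above the bound of -0.5 set beforehand. That setting keeps quantile normalization, and all changes shrank there (SD 0.58 to 0.39). The marker median was -0.56 under median scaling, where the median of all genes was 0.41 and 19 markers fell and 6 rose. Of the 36 markers, 31 lay below the median of all genes on the main values. The number was 30 under median scaling and 32 without background correction. A shift of all genes alike would not place them there. Brightness may still contribute through an effect that follows signal level, which was not tested for these markers. An effect of G-CSF on the marker genes themselves was not tested and stays open, as does the route by which G-CSF was given.

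Genes higher in tumor-bearing mice were often also higher with G-CSF, 227 against about 140.0 by chance. A larger share of neutrophils stays open. The value set beforehand for it was met, as the shared rises had a median of 0.95 with G-CSF, below the highest neutrophil marker (Mmp8, 1.13), but this sets a median against a maximum and decides nothing. The 781 genes higher in tumor-bearing mice, which were not chosen on G-CSF, had a median with G-CSF above that of the 9 neutrophil markers by 0.21 (0.19 against -0.02), 0.34 under median scaling and at lowest 0.12, without background correction, within the interquartile range of the markers (0.52, 0.56 and 0.52). This test replaced one on the shared rises, which were chosen for rising with G-CSF. Array brightness stays open. The ratio of the count to chance fell from 1.6 to 1.1 under median scaling (591 against about 529) and was 1.5 without background correction (296 against about 204). Median scaling sets each array by a probe near background and leaves the brightness of detected genes in place. The fall under it therefore cannot decide whether brightness made the overlap. Within 10 bands of genes by mean signal the common odds ratio was 1.98 on the main values and at lowest 1.16 (95% interval 1.01 to 1.33), under median scaling, and there without 1 array at lowest 1.05, with a lower limit of 0.92. Leaving out arrays was added after that first interval was seen, since genes are not independent. The correlation across genes, at lowest 0.26 under the other scalings, met the bound of 0.2 set beforehand, but that bound was wrong, since a shift of all genes alike leaves a correlation as it is. A response to G-CSF in both settings is a hypothesis that stays open beside these, since G-CSF was not measured in the mice.

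Genes changed at least 16-fold between fresh and cultured control cells (31 genes) had probes that did not always follow. Of 22 other detected probes 27.3% changed by less than 1 on the log2 scale or the opposite way, a share between the lower and upper bounds set beforehand. Within 1 experiment, for genes changed at least 4-fold, the share was 22.9% of 48 probes in tumor-bearing mice and 23.5% of 34 with G-CSF. Between the experiments it was 36.0% of 225 for genes changed 4- to 16-fold. The share is therefore not particular to the largest changes. Both shares between the experiments lay above both shares within 1 experiment, and this difference was not tested. An allele difference could act at any size of change, so the comparison of sizes cannot decide about it. Probes that fail on an allele stay open, for H2-K1 among others. For a strain or haplotype difference, the 9 genes that fell at least 16-fold held 0 neighbouring pairs in the genome, at or below the 95th percentile of random lists (1), which met the bound set beforehand as evidence against it. That bound was wrong as a reason to exclude it, since 0 lies 1 pair below it, within the spread of random lists (up to 6), and it left out the 22 genes that rose, which held 4 pairs against a 95th percentile of 2; this reading was adopted after the result was seen. Among genes changed at least 4-fold, most of which are not in the pattern, the 136 that fell held 21 pairs, also below the 95th percentile (26), and the 203 that rose held 71, above the highest of 10000 random lists (69). Falls and rises were counted apart, so a fall next to a rise made no pair. On chromosome 17 Psmb9 (place 237 in the order of tested genes) fell. Near it H2-K1 (227), H2-Eb1 (243) and H2-Ea (245) rose. Abhd16a (277) fell near Tnf (286) and H2-Q6 (294), which rose. These places were read after the result was seen, and pairs of a fall with a rise were not tested. A strain difference therefore stays open. Culture itself, which the design names, was not separable from the experiment and stays open.

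For the G-CSF count, 1 of 10 splits of the 6 cultured arrays into 3 and 3 called as many genes, the real one with 2485, and the highest other called 0. The 10 splits are too few for a share below 0.05.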

How the results depend on the processing

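The alternatives given here were fixed before the data were seen. Without background correction, the counts were 2284 for tumor-bearing mice, 2903 for G-CSF and 3482 for culture, and the authors' processed values gave the same counts. The tumor-bearing count lay between 1504 (no filter) and 2510 (intensity trend) under the settings with 1 probe per gene and all arrays, and the replicate block gave 2316. With every probe as its own feature the counts were 3509, 4047 and 5905, as more features were tested. Median scaling gave 4512 genes for G-CSF, 88.9% of them higher, and the arrays with G-CSF are brighter; for culture it gave 3410, of which 35.0% were higher. With a detection p-value below 0.01 on every array 3 genes passed in the G-CSF by CCL5 difference (Pi4k2b, Slc37a3 and Top1), and the cause was not tested. Leaving out 1 array in turn gave 1175 to 2133 genes for tumor-bearing mice, 1420 to 2040 for G-CSF, 2168 to 3322 for culture, 0 to 1 for CCL2 and for CCL2 against CCL5, 0 for CCL5, 0 to 3 for G-CSF by CCL2 and 0 for G-CSF by CCL5; where this leaves a group with 1 array, that array is assumed to vary like the others. The set higher in tumor-bearing mice moved with G-CSF by a median of 0.15 to 0.34 when 1 array was left out. With an estimated correlation the set medians of 0.19 and -0.19 lost their calls (adjusted p = 0.332 and 0.302), and 0 gene lists were called in any comparison, against 13 for tumor-bearing mice, 9 for G-CSF, 2 for culture and 1 each for CCL2 and both differences. Fry, which does not compare members with other genes, called 15, 10 and 18 lists in the first 3, 1 for G-CSF by CCL2 and 0 in the others. The calls lost with an estimated correlation cannot show that lists stayed still, since that test has 2 to 4 residual degrees of freedom. In tumor-bearing mice the T cell list lost its call at an estimated correlation of -0.248, below the preset 0.01, and the B cell list at 0.365, above it. Adjusted over the list alone, 1 member passed for CCL5, 2 for CCL2 against CCL5, 5 for G-CSF by CCL2 and 6 for G-CSF by CCL5, against 0 over all genes, as fewer genes are corrected for. Ccr3 in culture ranged from -0.77 to 1.12 when 1 array was left out, the latter (adjusted p = 0.0245) without the untreated cultured array, where the level comes from the other cultured arrays. Named genes were counted once per comparison and setting, including settings that give the same or nearly the same fit. They stayed on the same side of the test in 4304 cases, no longer passed in 201 and newly passed in 8. In 1 case the sign changed where either fit passed. Sign changes where neither fit passed lie within the 4304 and were not counted apart. The 4304 also hold the named genes of the chemokine effects and of both differences. There 0 genes passed in the main fit, so a loss was not possible. For named genes of the G-CSF effect with 1 array left out, 404 cases stayed, 62 no longer passed and 2 newly passed. Signal over background limits dim genes, as only 29.2% to 32.8% of probes were detected. The chip block was not run.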

Other observations

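The genes named here were chosen after their values were seen, and no test was added for them. Of the 218 genes called in opposite directions, Egr2, an immediate early transcription factor, rose by 1.82 in tumor-bearing mice on the log2 scale and changed by -1.50 with G-CSF in culture. Tlr4 stood at 1.02 and -1.47 (other probes -1.29 and -0.26 with G-CSF), Il1rap, a subunit of the interleukin 1 receptor, at 1.59 and -1.09, and the G protein-coupled receptor gene Gpr35 at 0.94 and -1.63. In the other direction Tnfrsf13b, a receptor of B cells for BAFF, stood at -2.25 in tumor-bearing mice and 1.03 with G-CSF and Kcnab2 at -1.45 and 1.24. On the same arrays other-cell markers had medians of -1.08 and -0.98.

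Further genes shared between tumor-bearing mice and G-CSF were Prnp, the prion protein gene (2.82 and 2.68), Gpc3 (1.86 and 2.37) and Ffar2, a receptor for short-chain fatty acids (1.61 and 1.84). Among the shared falls were the B cell genes Pou2af1 (-2.27 and -1.88) and Cd72 (-2.30 and -1.71). Scgb1a1, a secreted protein of airway epithelium, had changes with a standard error of 0.88 in the G-CSF effect, where its value was 0.80 (adjusted p = 0.543).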
